A study of Mus musculus with 9 samples.

How the data were processed

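Total RNA of 9 mouse T-cell lymphomas was hybridised to Affymetrix Mouse Genome 430 2.0 arrays after biotin labelling. The deposited table holds 1 intensity for each of 45101 probe sets and each array, computed by the authors with MAS5, per the submitters' processing notes; version, settings and the target of any scaling are not given in the sources used here. The deposited intensities are on a linear scale, with array medians from 39.8 to 43.8, maxima from 22800 to 24844 and a lowest value of 0.75. The array medians were close to each other, so no further normalisation was applied. The upper quartile of the signals did differ by group, from 194 to 201 in the ALT arrays and from 205 to 210 in the others. No 2 arrays were identical. The table holds no detection calls, so the level of background is unknown; the number of arrays limits the precision. The submitters' labels gave the group of every array, and all sample columns were used.

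Probe sets were joined to genes through the reference annotation of the array: 34958 named a single gene, 932 several and 9211 none, and 64 of the probe sets were controls. The RefSeq annotation of GRCm38.p6 gave chromosome and gene order; coordinates are not printed. Of the single-gene probe sets 34754 were in that annotation, and 0 had a symbol that differed. For each of 18194 genes the probe set with the highest mean over all 9 arrays was kept. Genes whose mean lay in the lowest 40% of probe sets were left out, which gave 12361 tested genes. Of 739 genes in the fixed lists 680 matched a probe set; the others were not analysed here. At 167 tested genes different probe sets passed in both directions, and 137 of 1250 called genes with several probe sets had a probe set that pointed the other way.

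Values were analysed as log2 of the signal plus 16. The 5 ALT tumours were compared with the 3 telomerase tumours, all at passage 4, with limma 3.58.1 in R 4.3.3 (a linear model per gene, moderated with an intensity trend, two-sided test, Benjamini-Hochberg adjustment over all tested genes, threshold 0.05). The parental tumour has no replicate and was kept out of the model; it was only described by which group mean it lay nearer to. Fixed gene lists, cell type lists and chromosomes with at least 50 tested genes were tested with camera of limma at a preset correlation between genes of 0.01, each family adjusted separately, for sets of at least 5 tested genes. Members of a list were also counted with p adjusted over the list alone. The genes named are the 10 in each direction with the largest change among those past the threshold whose groups did not overlap, a fixed set of telomere, mitochondrial and cell cycle genes, up to 4 members of each fixed list with the smallest p, and sex-linked genes; from the list members the text gives examples picked after their values were seen, mostly those whose call held whichever array was left out. These choices except that pick, the lists, and the other settings except those tied to pancreatic transcripts were made before the data were examined. Plots were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

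The other settings changed 1 choice at a time: no expression filter or a filter at 60%, a pseudocount of 1 or 64, quantile normalisation or median centring, the mean of all probe sets of a gene or each probe set on its own, the parental tumour added to the telomerase group or fitted as a group of its own, replicate numbers as a block, the variance model without trend or with robust moderation, each array left out in turn, an adjusted p of 0.1, a log2 change of at least 1, an estimated correlation between genes in camera, and fry. The p-values of fry are those for a common direction unless called mixed. After the data had been seen, transcripts of pancreatic acinar cells in 4 arrays led to 3 more settings: a term for these transcripts, and comparisons within the arrays without them and with them. Lists of acinar, islet, skeletal muscle, germline and ATF4 target genes, windows of 20 neighbouring genes (up to 39 in the last of a chromosome), and the tests that use them were also chosen then. The model was tested on simulated data with the spread of these arrays and 200 changed genes: it recovered 28% of changes of 0.5 on the log2 scale, 82% of changes of 1 and 96% of changes of 2, with 9 false calls among 12361 genes. The real comparison called 2161 genes, so these shares need not hold for it. The sex-linked genes were measured as a check of the animals: Xist had a log2 change of 0.42 (adjusted p = 0.371), and the Y-linked Eif2s3y, Kdm5d and Uty lay below the filter in both groups.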

Results

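The series profiled T-cell lymphomas of late-generation (G3) mice that lack Atm, a kinase that signals DNA breaks, and carry TERT-ER, a telomerase reverse transcriptase fused to the oestrogen receptor. In such cells 4-hydroxytamoxifen (4-OHT) switches telomerase on, and its withdrawal switches it off. The tumours were passaged in SCID mice, which lack mature B and T cells of their own. Tumours kept on 4-OHT are the telomerase group, and tumours kept on vehicle came to maintain telomeres by alternative lengthening of telomeres (ALT), a process based on recombination. There were 9 arrays of total RNA, of which 3 were telomerase tumours at passage 4, 5 were ALT tumours at passage 4 and 1 was the parental tumour. The submitters labelled the parental tumour as telomerase-positive. Each array gave a signal for 45101 probe sets. The median signal per array lay between 39.8 and 43.8, and between 28.2% and 30.7% of the probe sets of an array were below 16. The number of arrays limits the precision, and whether tumours of a group came from separate animals is not given in the sources used here, so the p-values measure only the spread between these samples.

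The comparison of ALT with telomerase tumours asks which transcripts set tumours with ALT apart from tumours of the same parental lines that kept telomerase. The telomerase tumours were kept on 4-OHT and the ALT tumours on vehicle. Effects of the drug, of active telomerase and of ALT therefore cannot be told apart here. The largest rise was in Rhox5, an X-linked homeobox gene normally active in reproductive tissue, with a signal of 7356 ± 274 (SD, n = 5) in ALT tumours and 40.8 ± 2.86 (SD, n = 3) in telomerase tumours (log2 change 7.02, SE 0.0728, limma adjusted p = 6.99e-12). Dppa4, a gene of pluripotent cells, rose from 19.5 ± 3.86 to 720 ± 224 (log2 change 4.33, adjusted p = 5.16e-06), and Gtsf1, which acts with the piRNA machinery, rose from 123 ± 16.1 to 2594 ± 251 (log2 change 4.23, adjusted p = 1.43e-08). The largest fall was in Trgv4, a variable segment of the T-cell receptor gamma locus, from 1964 ± 923 to 39.8 ± 71.2 (log2 change −5.69, SE 0.658, adjusted p = 0.000465). Trgv1, another segment of that locus, fell by 4.05 on the log2 scale, and Aldh18a1, which makes the precursor of proline, fell from 1206 ± 94.2 to 36.1 ± 27.3 (log2 change −4.69, adjusted p = 4.86e-05), with lower values in each of its 5 tested probe sets. The plot of array signals for selected genes shows these values tumour by tumour.

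The remaining large rises were in Slfn4 (log2 change 5.24), the X-linked Nxf3 (5.21), Wfdc15a (4.65), the X-linked Bex2 (3.78), Cfap43 (3.68), Fbxl16 (3.68) and Slc9b1 (3.55). The remaining large falls were in Fgfbp1 (−4.02), the chemokine genes Ccl8 (−4.00) and Ccl12 (−2.90), the homeobox gene Hoxa11 (−3.57), the cadherin gene Fat4 (−3.34), Gzma (−3.10), which encodes a protease of cytotoxic granules, and Card10 (−2.91). Where a group lies near or below the pseudocount of 16, as for Nxf3 and Slc9b1 (means of 6.55 and 7.01 in telomerase tumours) and Hoxa11 and Fat4 (9.04 and 11.0 in ALT tumours), the size and order of the log2 changes depend on it: Nxf3 had 6.77 with a pseudocount of 1 and 3.64 with 64, and Hoxa11 −4.94 and −2.23. In each of these 20 genes all 5 ALT values lay on one side of all 3 telomerase values, and 19 of the 20 stayed past the threshold whichever array was left out. The exception was Gzma, whose signal fell from 8591 ± 2725 to 1703 ± 2026 with an adjusted p of 0.0274. Its adjusted p was 0.0702 without telomerase 1, 0.0804 without telomerase 2, 0.0869 without telomerase 3, 0.0609 without ALT 1 and 0.0539 without ALT 2.

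Of 12361 genes tested, 2161 passed an adjusted p of 0.05, with 923 higher and 1238 lower in the ALT tumours; with quantile normalisation 1113 were higher and 1029 lower. A log2 change of at least 1 was seen in 449 of them, 181 higher and 268 lower. In 3050 of the tested genes (24.7%) the groups did not overlap, against 3.57% by chance. Without telomerase 1 the number past the threshold was 1152. In the comparison of arrays that lack pancreatic transcripts (2 telomerase and 2 ALT tumours, described with the cell type markers) 837 genes passed, and in the comparison of arrays that carry them (1 and 3 tumours) 334 passed. The second of these rests on a single telomerase tumour, which is assumed to vary like the ALT tumours.

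**Figure D1:**
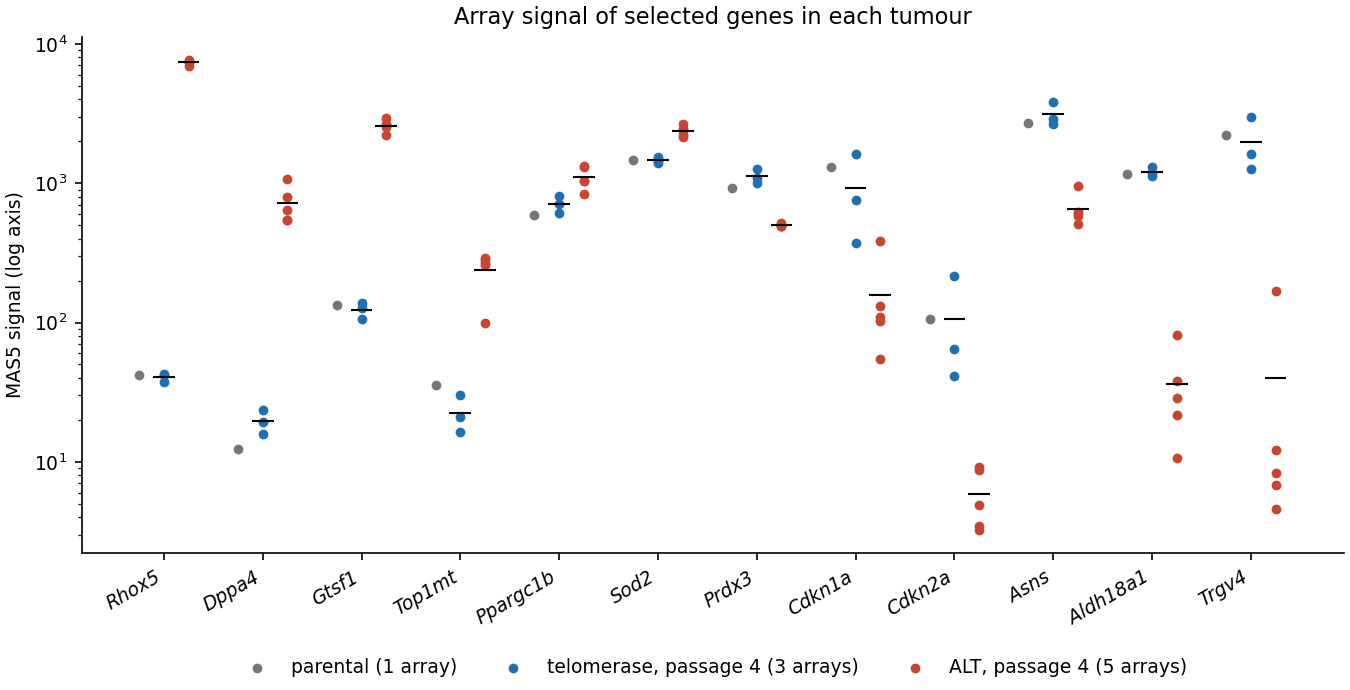
Array signal, on a log axis, of 12 genes in the parental tumour (grey), 3 telomerase tumours (blue) and 5 ALT tumours (red); each point is 1 array and each bar is a group mean. Rhox5, Dppa4, Gtsf1, Top1mt, Ppargc1b and Sod2 were higher in ALT tumours, and Prdx3, Cdkn1a, Cdkn2a, Asns, Aldh18a1 and Trgv4 were lower; the groups overlapped for Cdkn1a, where the highest ALT value was 386 and the lowest telomerase value 371.

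The mouse Tert probe set gave 44.5 ± 8.19 in telomerase tumours and 42.1 ± 15.8 in ALT tumours (adjusted p = 0.824); whether it reads the TERT-ER transcript is not given in the sources used here. Atrx and Daxx, chromatin genes often lost in human tumours with ALT, had log2 changes of −0.02 (adjusted p = 0.917) and −0.09 (adjusted p = 0.553). The shelterin genes Terf1 and Terf2 had log2 changes of 0.22 (adjusted p = 0.107) and 0.26 (adjusted p = 0.236). Atm had a log2 change of −0.12 (adjusted p = 0.681); all tumours carry the Atm deletion, and the position of its probe set relative to the deletion was not analysed here.

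Among genes tied to ALT, 4 of 42 rose and 4 fell, the same numbers when adjusted over the list alone; with the mean of probe sets 1 rose and 5 fell, and with quantile normalisation 4 rose and 2 fell. Mre11a, part of the complex that processes DNA breaks, rose by 0.65 on the log2 scale (adjusted p = 0.00475), and Rpa3, a subunit of the single-strand binding protein, fell by 0.67 (adjusted p = 0.00303). Of 21 checkpoint genes 2 rose and 3 fell (2 and 4 adjusted over the list alone), among them H2ax, the histone variant marked at breaks, which fell by 0.49 (adjusted p = 0.00169). Of 23 DNA replication genes 2 rose and 0 fell, also when adjusted over the list alone; the origin licensing gene Cdt1 rose by 0.72 (adjusted p = 0.00128) and lies in the distal part of chromosome 8, where neighbouring genes were higher as well. Gins2, the other replication gene that rose (log2 change 0.53), also lies on chromosome 8. So do Fanca and Terf2ip, which rose among the genes tied to ALT and the shelterin and CST genes. Of 10 genes of the telomerase complex 0 rose and 2 fell (0 and 3 adjusted over the list alone), and of 14 shelterin and CST genes 2 rose and 1 fell, also over the list alone. Without telomerase 1, 2 rose and 1 fell among the genes tied to ALT, 0 and 1 among the checkpoint genes, 1 and 0 among the DNA replication genes, and 0 passed in the telomerase complex or among the shelterin and CST genes, where 0 passed without the expression filter as well. None of these 5 lists passed the camera test (adjusted p from 0.648 to 0.773).

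Mitochondrial genes changed in both directions. Ppargc1b, a coactivator of mitochondrial biogenesis, rose from 711 ± 94.4 to 1107 ± 207 (log2 change 0.62, SE 0.156, adjusted p = 0.0236), and Pprc1, of the same family, rose by 0.55 (adjusted p = 0.00397). Ppargc1a was below the expression filter, with mean signals of 5.31 and 13.1. Sod2, the manganese superoxide dismutase of the mitochondrial matrix, rose from 1469 ± 75.8 to 2384 ± 199 (log2 change 0.69, SE 0.0830, adjusted p = 0.000542). Top1mt, the mitochondrial topoisomerase, rose from 22.5 ± 6.91 to 240 ± 80.0 (log2 change 2.67, adjusted p = 0.000465), and the matrix peroxidase Prdx3 fell from 1127 ± 135 to 498 ± 10.4 (log2 change −1.15, adjusted p = 6.25e-05). The Ppargc1b call was lost without telomerase 1 (adjusted p = 0.0779) and without telomerase 3 (0.0877), and within the arrays without pancreatic transcripts (log2 change 0.44, 0.0913) and with them (0.86, 0.165). The Sod2 call was lost when all its probe sets were averaged (log2 change 0.21, adjusted p = 0.139).

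By list, 4 of 15 genes of the PGC network rose and 1 fell (6 and 2 adjusted over the list alone); the deacetylase gene Sirt3 fell by 0.64 (adjusted p = 0.00122). Of 69 nuclear genes of oxidative phosphorylation 4 rose and 11 fell (5 and 11 adjusted over the list alone), among them Ndufa4, which fell by 0.71, and Uqcrfs1, which fell by 0.58 and lies on chromosome 13, where most called genes were lower. With quantile normalisation 4 of the 69 rose and 6 fell, and with median centring 4 rose and 7 fell. Of 52 mitochondrial ribosome genes 1 rose and 5 fell (1 and 2 over the list alone), and Mrpl32, also on chromosome 13, fell by 0.83. Of 16 genes of mitochondrial DNA maintenance 2 rose and 1 fell, of 17 genes of fatty acid oxidation 0 rose and 2 fell, and of 22 genes of the TCA cycle 2 rose and 3 fell, with the same numbers adjusted over each list alone. Of 22 genes of oxidative defence 3 rose and 4 fell, also adjusted over the list alone; the cytosolic dismutase gene Sod1 fell by 0.50 (adjusted p = 0.000811). Without telomerase 1, 1 rose and 1 fell in the PGC network, 1 and 6 in oxidative phosphorylation, 0 and 1 in the mitochondrial ribosome, 1 and 0 in mitochondrial DNA maintenance, 0 and 1 in fatty acid oxidation (0 and 0 without telomerase 2 or 3), 0 and 2 in the TCA cycle and 2 and 3 in oxidative defence. None of these 7 lists passed the camera test (adjusted p from 0.43 to 0.996). For the TCA cycle the median log2 change was 0.0138, and the mean, −0.0196, and the test pointed the other way.

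Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, fell from 919 ± 647 to 157 ± 131 (log2 change −2.45, SE 0.554, adjusted p = 0.0141), and Cdkn2a, which encodes p16 and p19Arf, fell from 107 ± 93.9 to 5.91 ± 2.87 (log2 change −2.23, SE 0.381, adjusted p = 0.00358). The ALT signals of Cdkn2a lay below the pseudocount, so the size of its log2 change depends on it (−1.16 with a pseudocount of 64, adjusted p = 0.0127). Of 18 targets of p53 measured, 0 rose and 4 fell (0 and 7 adjusted over the list alone, 0 and 2 without telomerase 1), including Zmat3, which fell by 1.82 (adjusted p = 0.00565), and Ei24, which fell by 0.96 (adjusted p = 0.00516). The list had a median log2 change of −0.398 and missed the camera threshold (adjusted p = 0.0565; p = 0.15 and adjusted p = 0.968 with an estimated correlation). Over the other settings its adjusted p ran from 0.000109, in arrays without pancreatic transcripts, to 0.671, in arrays with them. Cdkn1a, Zmat3 and Ei24 were highest in telomerase 1 (1633, 2024 and 1692) and the parental tumour (1311, 1996 and 1656), the tumours that also carried skeletal muscle transcripts. Without telomerase 1 the Cdkn1a change was −1.92 with an adjusted p of 0.0693, and in the arrays with pancreatic transcripts it was −0.99 with an adjusted p of 0.451.

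Of 24 cell cycle genes 3 rose and 1 fell, and Kif11, the mitotic kinesin, fell by 0.83 (adjusted p = 0.0062). Of 17 apoptosis genes 2 rose and 1 fell. Of 19 targets of Myc 2 rose and 2 fell, and Myc itself had a log2 change of −0.21 (adjusted p = 0.347). These counts were the same adjusted over each list alone. The balance of the cell cycle genes turned with the mean of probe sets, where 0 rose and 3 fell. Without telomerase 1, and with replicate numbers as a block, 0 cell cycle genes rose and 1 fell; without telomerase 1, 0 apoptosis genes passed, and 1 Myc target rose and 1 fell. Of 25 cytosolic ribosome genes 0 passed the limma test, over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05. None of the 4 lists passed the camera test (adjusted p from 0.355 to 0.983). For the Myc targets the median, −0.068, and the test pointed down and the mean, 0.0311, pointed up.

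Asns, the asparagine synthetase, fell from 3113 ± 616 to 652 ± 174 (log2 change −2.24, adjusted p = 9.73e-05), and Trib3, a pseudokinase induced under stress, fell by 1.70 (adjusted p = 0.000821). They are 2 of the 3 genes that fell among 16 genes of the unfolded protein response, where 1 rose (7 rose and 5 fell adjusted over the list alone, 0 and 3 without telomerase 1, 4 and 2 without telomerase 3, and 5 and 3 with quantile normalisation). The median of that list, 0.213, had the opposite sign to its mean, −0.224, and to its test (adjusted p = 0.996). Xbp1, a transcription factor of secretory cells in that list, was at 2308 and 2088 in telomerase 1 and 2 and at 3751 in telomerase 3, which carried pancreatic transcripts, and at 3330 and 3647 in ALT 3 and 4, which did not (log2 change 0.52 between the groups, adjusted p = 0.0756).

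Of 18 genes of glycolysis 2 rose and 3 fell (3 and 3 adjusted over the list alone), and Pkm, the pyruvate kinase, fell by 0.69 (adjusted p = 0.00562). Of 14 hypoxia genes 2 rose and 3 fell (5 and 3 over the list alone); Ndrg1 fell by 1.28 (adjusted p = 0.00124) and P4ha2, a collagen prolyl hydroxylase, fell by 1.28 (adjusted p = 0.0026). Of 16 genes of cholesterol synthesis 2 rose and 1 fell (3 and 2 over the list alone), and Idi1, on chromosome 13, fell by 0.87 (adjusted p = 0.00269); the median of this list was −0.0139 and its mean, 0.0127, and test pointed up. Of 8 oestrogen response genes 2 rose and 1 fell (3 and 1 over the list alone), with Greb1 rising by 0.78 (adjusted p = 0.00108), Ccnd1 rising by 1.16 (adjusted p = 0.0073) and Igfbp4 falling by 1.03 (adjusted p = 0.0115, and 0.0617 without telomerase 1). Only the telomerase tumours were kept on 4-OHT, a ligand of the receptor part of TERT-ER, so drug and ALT cannot be told apart for these genes. Of 23 interferon response genes 0 rose and 2 fell, also over the list alone; without telomerase 2, 0 passed, and without telomerase 1 these 2 were lost and 2 others fell. Of 10 NOTCH pathway genes 1 rose and 3 fell (1 and 4 over the list alone), and Nrarp, a feedback inhibitor of NOTCH, fell by 1.46 (adjusted p = 0.000271). Without telomerase 1, 1 rose and 2 fell in glycolysis (0 and 1 without telomerase 2), 0 and 2 in hypoxia, 2 and 1 in cholesterol synthesis, 2 and 0 in the oestrogen response and 1 and 1 in the NOTCH pathway. Of the 24 pathway lists 0 passed with limma camera, with camera and an estimated correlation, or with fry, each for a common direction. At an unadjusted p of 0.05 camera called 1 list, the p53 targets (p = 0.00236), camera with an estimated correlation called 0 and fry called 5. The mixed p of fry, for changes in either direction, ran from 5.23e-10 (mitochondrial ribosome) to 0.0227 (DNA replication). It does not compare a list with the other genes.

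Markers of T cells changed in both directions. Of 19 T-cell genes 3 rose and 6 fell (3 and 7 adjusted over the list alone): Lef1, a transcription factor of T-cell development, fell by 1.20 (adjusted p = 7.93e-05), the receptor component Cd3g fell by 0.82 (adjusted p = 0.000759), and Cd2 and Cd8b1 rose by 0.94 and 0.96 (adjusted p = 0.00367 and 0.00362). Of 11 immature thymocyte genes 2 rose and 2 fell (3 and 2 over the list alone), of 17 myeloid genes 1 rose and 1 fell, of 9 endothelial genes 0 rose and 2 fell (0 and 3 over the list alone), and of 5 cytotoxic cell genes 0 rose and 1 fell. None of 15 stromal and 6 B-cell genes passed, and 1 of 10 genes of adipose, muscle and epithelial tissue fell. Counts given without a second pair were the same adjusted over the list alone. Without telomerase 1, 2 T-cell genes rose and 5 fell, 1 endothelial gene rose and 0 fell, and 0 passed among the immature thymocyte, myeloid, cytotoxic cell and other tissue genes. Of the 8 cell type lists 0 passed the camera test (adjusted p from 0.42 to 0.575) and 0 passed with an estimated correlation or with fry. In these tests for a common direction 0 had an unadjusted p under 0.05. The mixed p of fry, for changes in either direction, was 5.72e-07 for T-cell and 7.84e-06 for immature thymocyte genes. It was 0.00329 for myeloid and 0.0087 for endothelial genes, and from 0.0566 to 0.709 for the other lists. Erythroid and liver markers had only 4 and 3 tested genes, too few for a test.

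Transcripts of pancreatic acinar cells were high in arrays of both groups, and those of skeletal muscle in the parental tumour and telomerase 1. The 19 genes of pancreatic acinar cells had a mean log2 signal of 12.1 in telomerase 3, 11.4 in ALT 1, 12.4 in ALT 2 and 12.9 in ALT 5, and between 5.02 and 6.02 in the other 5 arrays. Cela3b, an acinar elastase, averaged 19790 in the former and 66.7 in the latter. Skeletal muscle transcripts were high in the parental tumour and in telomerase 1, where Acta1, the muscle actin, reached 3148 and 2428, with 184 in telomerase 2 and at most 34.3 elsewhere. No term was fitted for muscle transcripts. With the acinar transcripts as a term in the model 1893 genes passed. Of 111 genes named here or in the full set of list examples that passed, 102 still passed with that term, 55 in the comparison of arrays without acinar transcripts and 27 in that of arrays with them.

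**Figure D2:**
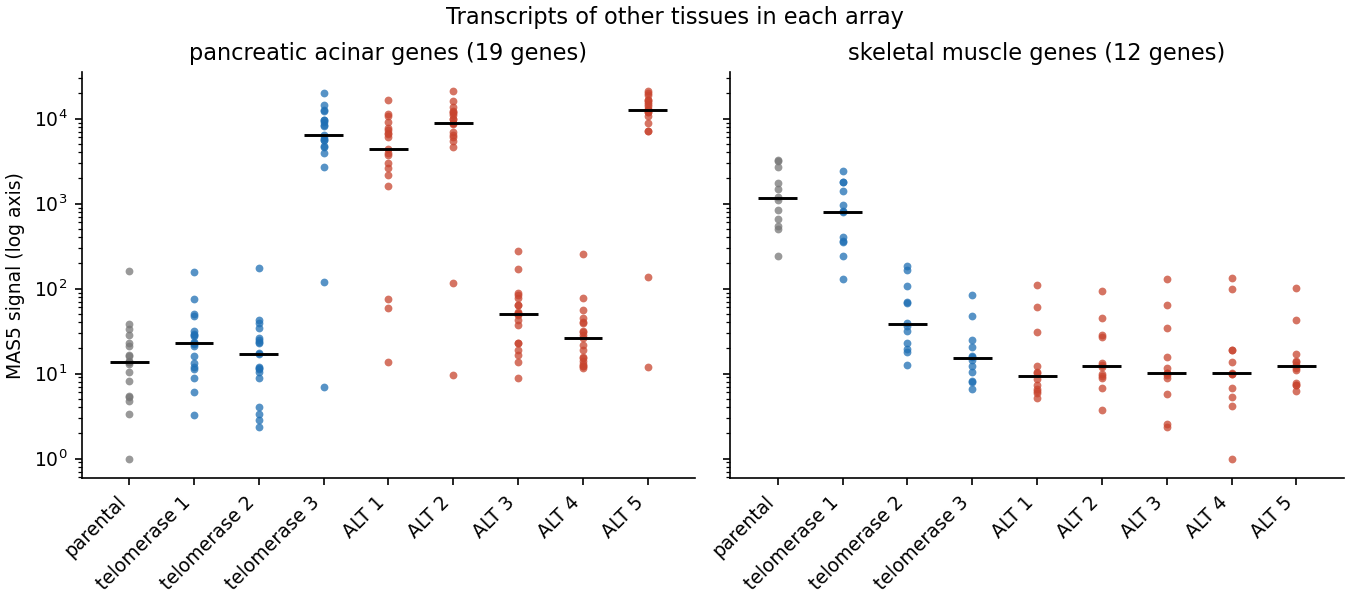
Array signal, on a log axis, of 19 pancreatic acinar genes (left) and 12 skeletal muscle genes (right) in each of the 9 tumours; each point is 1 gene and each bar is the median of the list. Acinar transcripts were high in telomerase 3 and ALT 1, 2 and 5, and muscle transcripts in the parental tumour and telomerase 1.

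On chromosome 13, 177 of 447 tested genes fell and 9 rose, with a median log2 change of −0.366. On chromosome 8, 122 of 654 rose and 36 fell, with a median of 0.111, and on chromosome 18, 66 of 299 rose and 33 fell, with a median of 0.19. The camera test called these 3 chromosomes (adjusted p = 7.23e-15 for chromosome 13 and 0.000806 for each of the others). With an estimated correlation between genes 0 passed, and 2 had an unadjusted p under 0.05 (adjusted p = 0.286 for chromosomes 13 and 8, and 0.958 for chromosome 18). In the arrays without pancreatic transcripts chromosome 18 had a median of 0.125 and an adjusted p of 0.305.

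Within these chromosomes the size of the shift varied. Among 606 windows of neighbouring tested genes, of 20 genes each except for up to 39 in the last window of a chromosome, 36 had a median log2 change of at least 0.3 in size, 12 higher and 24 lower, and 14 of the lower windows were on chromosome 13, where all 22 windows had a negative median, up to −0.0553. The lowest of them, from Dbn1 to 2210016F16Rik, had a median of −0.796, and the window that begins with Trgv4 had −0.494. On chromosome 8 the 8 higher windows lay between Cfap20 and Cdt1, in the distal part, and on chromosome 18 the last window, of 39 genes from Myo5b to Tmx3, had a median of −0.549 while the window next to it, from Cep192 to Mbd1, had 0.392. These windows held 349 of the 2161 called genes (16.1%).

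**Figure D3:**
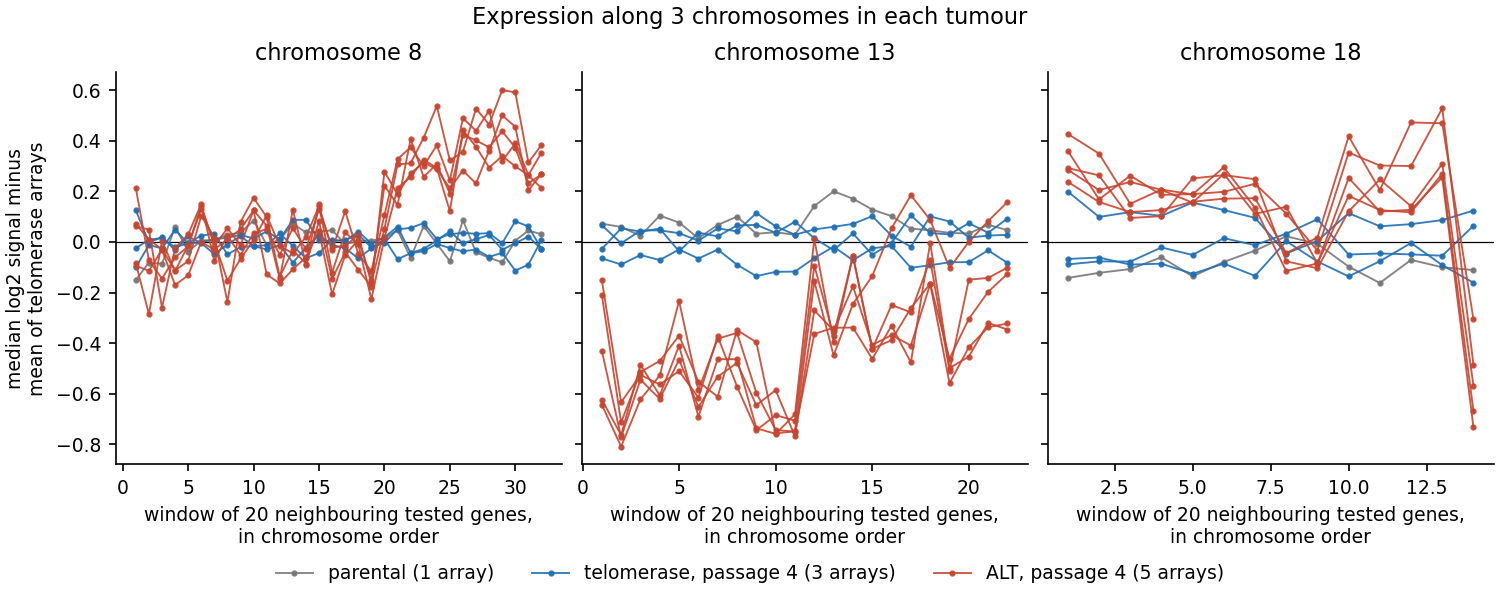
Median log2 signal of windows of 20 neighbouring tested genes (up to 39 in the last of a chromosome) along chromosomes 8, 13 and 18, minus the mean of the 3 telomerase tumours; each line is 1 tumour (grey parental, blue telomerase, red ALT). The ALT tumours were higher over distal chromosome 8, lower over much of chromosome 13 and lower at the end of chromosome 18.

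The single parental tumour was compared with both groups to see on which side it lay, without a test. The parental tumour is itself labelled as telomerase-positive, so it is not a neutral baseline for the groups. At 2017 of the 2161 called genes (93.3%) its signal was nearer to the telomerase mean than to the ALT mean, at 89.5% of the genes higher in ALT tumours and 96.2% of those lower. Rhox5 had a parental signal of 41.8, Dppa4 12.3 and Gtsf1 134, close to the telomerase tumours, and Aldh18a1 had 1166 and Trgv4 2210. Ppargc1b had 588 and Sod2 1468, and Cdkn1a had 1311.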

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

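The checks of the acinar term, of array scaling, of gene order and of the neighbours of Ppargc1b were chosen after the result was seen. The bound for Ppargc1b was also changed after its value was seen. The splits of the arrays were planned.

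Acinar transcripts stood apart in 4 of 9 arrays, in genes outside the planned comparisons: the median of 19 acinar genes was 7.93 higher on the log2 scale in telomerase 3 and ALT 1, 2 and 5 than in the other arrays. The median of all tested genes differed by −0.0211, so the arrays were alike in general level. The array medians were already known to be close, so this value is a description and not a test of scaling. Host pancreas in the specimens stays open: the median of 11 islet genes was higher by 0.618 (one-sided exact permutation p = 0.00794 over all choices of 4 arrays), with Ins2 at 603 against 7.32 and Gcg at 170 against 8.32, but below the difference of 1 set for that test. Pancreatic tissue as the whole source of the differences between ALT and telomerase tumours is argued against, since 1893 genes passed with the acinar term, against 2161 without it. Expression of the acinar genes by the lymphoma cells themselves was not tested.

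Chance is argued against for the number of genes between ALT and telomerase tumours. Of the 56 splits of the 8 arrays into 3 and 5, only 1, the real one, gave as many as 2161, and the highest other gave 12. The real split is always counted, so 1 is the lowest result possible. The splits also treat the arrays as independent, and tumours of a group that share an animal or a lineage would give the same result. Chance cannot be excluded for the number of chromosomes past the camera test, where 33 of the 56 splits gave at least the 3 of the real split and the highest other gave 7.

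Runs of neighbouring genes shifted together in the ALT tumours, most of all on chromosomes 13 and 8. Chance order of genes is argued against, since 36 windows passed the limit and at most 2 did in 100 shuffled orders. The shuffles also break any shared expression that neighbouring genes have in general. Windows were not counted in the other splits of the arrays, so this test cannot tie the runs to ALT. Pancreatic tissue is argued against as well, since 97% of 33 windows chosen in the arrays without acinar transcripts had the same sign in the arrays with them. A copy number change shared by the 5 ALT tumours is a candidate explanation: in ALT 1, 2 and 5, which had no part in choosing the windows, at least 90.9% of the windows had the same direction. That test scored direction only, and ALT 3 and 4 helped to choose the windows. The lowest window of chromosome 13 was even, from −0.768 to −0.681 in the 5 tumours. Other windows were not: from Poc5 to Naip2 ALT 3 had −0.103 and the others −0.558 to −0.461. From Slain1 to Nalcn, on chromosome 14, ALT 5 had −0.0321 and the others −0.542 to −0.438. A shared copy number change is a hypothesis, since DNA was not measured here and regional control of transcription was not tested.

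Ppargc1b lies on chromosome 18, where 66 of 299 tested genes rose and 33 fell in the ALT tumours. A shift of its neighbourhood cannot be told apart from a change of the gene itself: 18 of its 20 nearest tested neighbours had a smaller log2 change than its 0.62, 2 rose by more (Slc26a2 by 0.81 and Bvht by 0.96), and their median was 0.178, with the middle of their range from 0.0135 to 0.402. A difference between ALT and telomerase in this gene alone stays open too, as untested.

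Among 218 groups of 5 ALT values, 9 held a value far from the other 4, about as chance gives, which marks 1 in 20 groups. On the log2 scale Trgv4 was 7.516 in ALT 4 (signal 167), with the others from 4.364 to 4.819. Nkg7 was 10.26 in ALT 4, with the others from 9.334 to 9.597. Suclg2 was 9.5 in ALT 2, with the others from 9.726 to 9.81. Bid was 8.301 in ALT 5, with the others from 8.79 to 8.871. Car2 was 5.186 in ALT 4, with the others from 5.971 to 6.234. Xbp1 was 12.21 in ALT 1, with the others from 11.71 to 11.85. Top1mt was 6.841 in ALT 5, with the others from 8.097 to 8.263. Ruvbl1 was 9.718 in ALT 1, with the others from 9.818 to 9.858. The median of chromosome 13 was −0.217 in ALT 3, with the others from −0.442 to −0.392. Among 4667 probe sets that name no single gene, which the gene comparison left out, 586 passed the same limma test, 201 higher and 385 lower.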

How the results depend on the processing

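The settings tied to acinar transcripts were chosen after the data were seen; the others were planned. The 2161 genes past the threshold became 4502 with each of 22367 probe sets tested on its own, since more were tested, 837 and 334 in the arrays without and with acinar transcripts, since fewer arrays were compared, and 449 with a log2 change of at least 1, by construction. With replicate numbers as a block 982 passed; the numbers are not said to pair the tumours, the deviations of equal numbers correlated at −0.3, −0.4 and −0.57, and the best partners of telomerase 1, 2 and 3 were ALT 3, 3 and 2, at 0.4, 0.42 and 0.45. Leaving out 1 array gave 1152 (without telomerase 1) to 2080 (without ALT 4). The count stayed within 1.5 times in the other settings, from 1893 to 3087, and of the called genes tested again 1 of 2150 changed sign with a pseudocount of 1 and 107 of 2115 with the mean of probe sets. The majority of lower genes turned with quantile normalisation (1113 higher, 1029 lower). The number of pathway lists past the camera test, 0, became 1, the p53 targets, with no filter, quantile normalisation, median centring, the parental tumour in the telomerase group, the replicate block, the acinar term and the arrays without acinar transcripts, and 2, cell cycle and DNA replication, in the arrays with them, where the 1 telomerase tumour is assumed to vary like the ALT tumours; leaving out 1 array gave 0 to 1 (the p53 targets at adjusted p = 0.0417 without telomerase 2, 0.00458 without telomerase 3, 0.0249 without ALT 1 and 0.0221 without ALT 5). The balance of rises and falls turned in at least 1 setting in the checkpoint (3 and 2 with the mean of probe sets), apoptosis (1 and 2 with it), cell cycle (0 and 3 with it), glycolysis (3 and 2 with quantile normalisation), unfolded protein response (5 and 3 with it), cholesterol synthesis (0 and 1 with the block), hypoxia (4 and 3 with the parental tumour in the telomerase group), shelterin and CST (0 and 1 with the acinar term) and endothelial lists (1 and 0 without telomerase 1); the even balance of the Myc targets became 0 and 3 with the mean of probe sets. Cell type lists stayed at 0. Chromosomes 13 and 8 passed in every setting except with an estimated correlation, where 0 passed; chromosome 18 also failed with fry (adjusted p = 0.0809), which called X (0.0332) and 16 (0.0374), and in the arrays without acinar transcripts (0.305), and chromosome 3 or 12 joined in some settings, to 4 at most. The share of called genes at which the parental tumour lay nearer the telomerase mean became 92.3% with the mean of probe sets, 96.2% with the block, 95.5% and 90.1% in the arrays without and with acinar transcripts, and 92.5% to 95.4% without 1 array. With the mean of probe sets, which brings in other probe sets of the gene, Nolc1 reversed to −0.18, Nusap1 to −0.40 (adjusted p = 0.0477) and Terf2ip to −0.00097. Where no cause is named, the cause was not tested. Of 111 named genes past the threshold, 57 stayed past it whichever array was left out. Genes with a mean log2 signal below 5.328 were tested only without the filter, and background was not measured.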

Other observations

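The test of X-linked genes was chosen after the result was seen, and the lists of germline genes and of ATF4 targets were written after the named genes had been seen but before their own members were tested.

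A list of 32 further targets of ATF4, the transcription factor of the amino acid response, had 29 tested genes, of which 8 fell and 1 rose, Stc2 (log2 change 0.60). Those that fell were Slc7a3 (−1.89), a transporter of basic amino acids, Atf5 (−1.50), the transaminase gene Gpt2 (−1.05), Phgdh (−0.48) and Psat1 (−0.52) of serine synthesis, and the tRNA synthetase genes Iars (−0.79), Lars (−0.63) and Sars (−0.32). The median log2 change of the 29 was −0.215, against −0.0305 for random lists matched on level, which placed it at percentile 0.24 of 10000 such lists. Such lists treat genes as independent, so the percentile leaves out correlation between the targets and the spread between tumours. Against the telomerase mean the median of the 29 was −0.305, −0.268, −0.152, −0.285 and −0.17 in ALT 1 to 5, and −0.0661, 0.0522 and −0.0519 in telomerase 1 to 3. The mean of their log2 signals did not separate the groups over all arrays, with 9.645 in ALT 5, as in telomerase 3, and 9.504 in telomerase 1. ALT 5 and telomerase 3 both carried acinar transcripts, and in ALT 5 Nupr1, a member of the list, reached 9245. In the arrays without acinar transcripts the mean was 9.504 and 9.689 in telomerase 1 and 2, and 9.344 and 9.219 in ALT 3 and 4. A broad decrease of ATF4 targets in the ALT tumours goes with the lower median of the 29, as a hypothesis only. Atf4 itself had a log2 change of −0.15 (adjusted p = 0.228), and Iars lies in the lower region of chromosome 13.

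Among 25 germline genes other than Rhox5, Dppa4 and Gtsf1, tested without the expression filter, 4 rose: Syce1 (1.89, adjusted p = 0.00317), Dppa2 (1.51, 0.00618), Piwil2 (0.91, 0.00332) and Sohlh2 (0.50, 0.0446). Tdrkh fell (−0.58, 0.0497). Their median log2 change was 0.137, against 0.0307 for matched random lists, at percentile 95.9, just past the 95% set for a broad release of germline genes. Many of the 25 had mean signals near or below the pseudocount of 16 in both groups, such as Stk31 (9.82 in telomerase and 9.65 in ALT tumours). The median over such genes cannot show a broad release. Dppa4 lies in a window of chromosome 16, from Usf3 to Morc1, whose median log2 change was 0.504.

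X-linked genes were over-represented among the largest rises: 5 of the 41 called genes that rose by at least 2 on the log2 scale were X-linked (Rhox5, Nxf3, Bex2, P2ry10 and Btk), against 360 of all 12361 tested genes (odds ratio 4.68, two-sided Fisher exact p = 0.00645). The pattern was noticed in the same genes that the test used, so the p-value is a description, and no explanation was tested.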
